A study of Mus musculus with 6 samples.

How the data were processed

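Droplet-based single-cell RNA libraries were made from mouse (C57BL/6) bone marrow with the Chromium Single Cell 3′ chemistry, per the labels' protocols. In this assay each droplet carries a short cell barcode that is read together with the 3′ end of each transcript. The labels describe 6 samples, 1 in each of 6 groups, so no group has a replicate sample. Of these, 5 are progenitor populations with 0 days of expansion and 1 is a culture expanded for 10 days with stem cell factor and 2i. The barcodes carry 8 library numbers, so whether a group held more than 1 library is unknown. What 2i contains is not given in the sources used here.

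The submitters' processing notes name bcl2fastq, Cell Ranger 2.1.0 and the mouse build mm10. The release of the gene annotation, the rule by which cell barcodes were kept and the treatment of doublets (barcodes that stand for more than 1 cell) are not given in the sources used here. The files analysed were a deposited list of cell barcodes, each with a library number as suffix, and a deposited list of gene identifiers paired with symbols. Both are text and carry no measurement. A matrix of counts was not analysed here. The planned comparison of expanded cells with the progenitor populations and the planned clustering were therefore not run. Total counts per library, counts per cell, expression values and cell types are not reported, and the depth is unknown. Each barcode has 16 bases. No doublets were called or removed here, so a count of barcodes is not a count of single cells. No library number matches the label of a sample, so none was given to a group, and all values below are values of library numbers.

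Barcodes were counted per library number, and barcode sequences present in both members of each of the 28 pairs of library numbers were counted by exact identity. The size of the pool from which barcodes were drawn was estimated as the sum over pairs of the products of the library sizes, divided by the sum of the shared sequences. Because this estimate uses the same pairs, it fixes the total expected sharing, and the test compares pairs with one another. Each pair was tested against its expectation with a 2-sided exact hypergeometric test, adjusted by the Benjamini-Hochberg method over the 28 pairs. The test was repeated with the pool estimated from the other pairs. Spread over all pairs was compared with 1000 shuffles of the library numbers (fixed seed). A shuffle that gave a sequence the same library number more than once was repaired by random swaps, which does not draw the permitted shuffles evenly. Intervals are 95% exact Poisson intervals for counts and 95% exact (Clopper-Pearson) intervals for percentages, and those of barcodes cover counting error only. Gene classes were counted in full, so the limits on their percentages measure no sampling error.

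The pair test was checked on simulated libraries of the real sizes, in 50 runs per setting over 28 pairs. With no added sharing, the pair of library numbers 1 and 4 was called in 0% of runs and another pair in 2%. With 30 added shared barcodes in that pair it was called in 18% of runs, with 60 in 94% and with 90 in 100%. Another pair was called in 0%, 12% and 12% of those runs.

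Gene identifiers were matched without version to GENCODE M21, an annotation of the mouse assembly GRCm38, which is the assembly called mm10 in the processing notes. This matched 27722 of 27998 identifiers (99.0%), and 276 had no match. All coordinates are 1-based GRCm38 coordinates from M21, which may differ from the annotation used for counting. Marker genes were fixed before the data were examined, as 82 genes in 11 lists. The rule for named genes was to name markers only as listed or not listed where no counts were used, and to name at most the first 10 repeated symbols in alphabetical order. A further list of 14 genes (stem cell factor, its receptor and antigens often used to sort progenitors) was chosen after the symbols had been seen.

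Overlap of a marker with other listed genes was measured as the bases among its last 500 exonic bases, over all M21 transcripts, that lie in exons of another listed gene on the same strand. Shared sequence was measured as the percentage of distinct 50-base words in the last 500 bases of the gene's transcripts that also occur in a transcript of another listed gene. A gene was counted as sharing sequence at 10% or more. Both measures were added after the data were examined, so the values they give for markers go beyond the rule for named genes, as does Itgam, a repeated symbol chosen after its values were seen. They cover all listed markers, and both describe the annotation, not reads. Read length and the handling of reads that fit several genes are not given in the sources used here. Alternatives were a pool estimated without each library number in turn, shuffled library numbers, identity or 1 mismatch, barcodes found in 1 library number, symbols matched without regard to case, symbols carried by 1 feature, windows of 200 and 1000 bases, 90-base words and protein-coding overlaps only. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.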

Results

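The study set out to compare the transcriptomes of cultured mouse bone marrow cells with those of stem and progenitor cells. The labelled samples were hematopoietic stem cells, common myeloid progenitors, granulocyte-monocyte progenitors, megakaryocyte-erythroid progenitors, common lymphoid progenitors and bone marrow cells expanded for 10 days with stem cell factor and 2i. Each was 1 labelled sample without a replicate sample. Counts of transcripts were not analysed here, so whether any gene was higher or lower in the expanded cells is not reported. The values below give which lineage genes the feature list could measure, how far their 3′ ends can be told apart from those of other listed genes, and how the cell barcodes fell into libraries.

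The marker genes were almost completely listed, as protein-coding genes were in general. Of 82 marker genes fixed before the data were examined, 81 were in the list of 27998 features, each under 1 identifier. Of all M21 protein-coding genes, 21631 of 22028 (98.2%) were listed, so this completeness is not particular to the markers. The hematopoietic stem cell list was complete with 11 of 11 genes. It included Procr, the endothelial protein C receptor (GRCm38 chromosome 2, 155751117 to 155755471), Hlf, a transcription factor gene (chromosome 11, 90336536 to 90390895), and Mecom, which encodes the transcription factor Evi1 (chromosome 3, 29951296 to 30548008). Slamf1, which encodes the surface antigen CD150, lay on chromosome 1 from 171767127 to 171801184. M21 annotates all of these as protein-coding.

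Myeloid and erythroid markers were listed in full. All 10 granulocyte-monocyte progenitor and neutrophil genes were present, among them the genes of the granule proteins Mpo (chromosome 11, 87793581 to 87804413), Elane (chromosome 10, 79886247 to 79888215) and Prtn3 (chromosome 10, 79874476 to 79883174). All 8 monocyte and macrophage genes were present, including Irf8, a transcription factor gene, and Csf1r, which encodes the receptor of macrophage colony-stimulating factor. The 9 erythroid genes included the transcription factor genes Klf1 (chromosome 8, 84901928 to 84905291) and Gata1 (chromosome X, 7959260 to 7978071). The 7 megakaryocyte genes included Pf4, platelet factor 4, and Vwf, von Willebrand factor. The lists for cells that a bone marrow sample or culture could also hold were complete as well, with 8 mast cell and basophil genes, 3 eosinophil genes, 4 dendritic cell genes and 5 stromal and endothelial genes. The 6 cell cycle genes, such as Mki67 and Top2a, were all listed.

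The lymphoid list was the exception, with 10 of 11 genes listed. Il7r, which encodes the interleukin 7 receptor, Dntt, which encodes terminal transferase, and Rag1 and Rag2, which encode the recombinase of antigen receptor genes, were present. Ighm, the constant region gene of the immunoglobulin mu heavy chain (chromosome 12, 113418558 to 113422730), was not. No immunoglobulin or T cell receptor gene of M21 was listed, with 0 of 432 immunoglobulin and 0 of 270 T cell receptor segments and pseudogenes. The exact upper limit for both classes together was 0.524%. By contrast, 21631 of 22028 protein-coding genes (98.2%, exact interval 98.0% to 98.4%) were listed. Long intergenic RNA genes were listed at 59.8% and antisense RNA genes at 77.1%. No microRNA gene of 2207 and no small nucleolar RNA gene of 1507 was listed.

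Most markers had 3′ ends of their own, and 5 of the 81 shared at least 10% of their 3′ end sequence with another listed gene. Hba-a1, an alpha globin gene, shared 91.1% of its 50-base words with Hba-a2. Hbb-bt, an adult beta globin gene, shared 64.5% with Hbb-bs. Gp1bb, which encodes a platelet glycoprotein, shared 59.2% with Sept5. Pcna, a replication factor gene, shared 20.99% with Pcna-ps2. Vpreb1, which encodes a part of the surrogate light chain, shared 20.9% with Vpreb2. Words were pooled over all transcripts of a gene, so genes with more transcript ends tend to get lower percentages. Pcna had 1272 words and Vpreb1 918, against 451 for Hbb-bt, so the percentages are not strictly comparable between genes. Ly6a, which encodes the stem cell antigen Sca-1, shared 6.03%, mainly with Ly6c1 and Ly6i, and was below the limit. Ly6a was at 17.7% with a window of 1000 bases and shared 0% with 90-base words. No shared 50-base word was found for 67 of the 81 markers, and no shared 90-base word for 76. By position, Gp1bb was the only fixed marker whose last 500 exonic bases lay in exons of another listed gene on the same strand. Of those bases, 315 (63%) were in exons of Sept5. Among all listed protein-coding genes, 394 of 21631 (1.82%) had such an overlap.

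**Figure D1:**
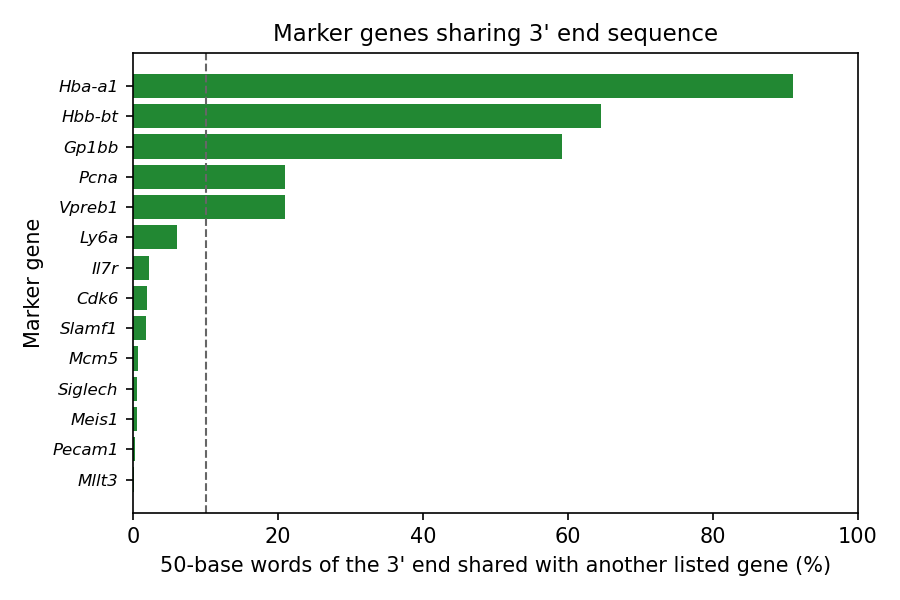
Percentage of distinct 50-base words in the last 500 bases of each marker gene's transcripts that also occur in another listed gene, for the 14 fixed markers with any shared word. The dashed line marks 10%, and Hba-a1, Hbb-bt, Gp1bb, Pcna and Vpreb1 lie above it.

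Some symbols stood for more than 1 feature. In all, 56 symbols were carried by 121 features. The first 10 in alphabetical order were 3110039M20Rik, 4930556M19Rik, Apoc2, Atn1, C1s2, Ccdc142, Ccl19, Ccl21a, Ccl21b and Ccl21c. Ccl19 and Ccl21a, which encode chemokines, each had 1 feature on chromosome 4 and 1 on the scaffold JH584294.1 in M21. Both features named Apoc2 shared most of their last 500 exonic bases with another listed feature, at 96.6% and 100%. For the first, that was the other Apoc2 feature alone. Both features named Ccdc142 were at 100%, and over all exons 1 of them also overlapped Mrpl53. Those named Atn1 were at 100% and 26.4%, and over all exons the first also overlapped Grcc10. These percentages count overlap with any other listed feature, not only with the feature of the same symbol.

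The barcode list held 63316 cell barcodes under 8 library numbers, 2 more than the 6 labelled samples. Library number 1 held 13018 barcodes, library number 2 held 7523, library number 3 held 9591 and library number 4 held 7676. Library number 5 held 10116, library number 6 held 4301, library number 7 held 5776 and library number 8 held 5315. The median was 7599.5. No name tied a library number to a population, so the number of stem cells, progenitors or expanded cells is not given.

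**Figure D2:**
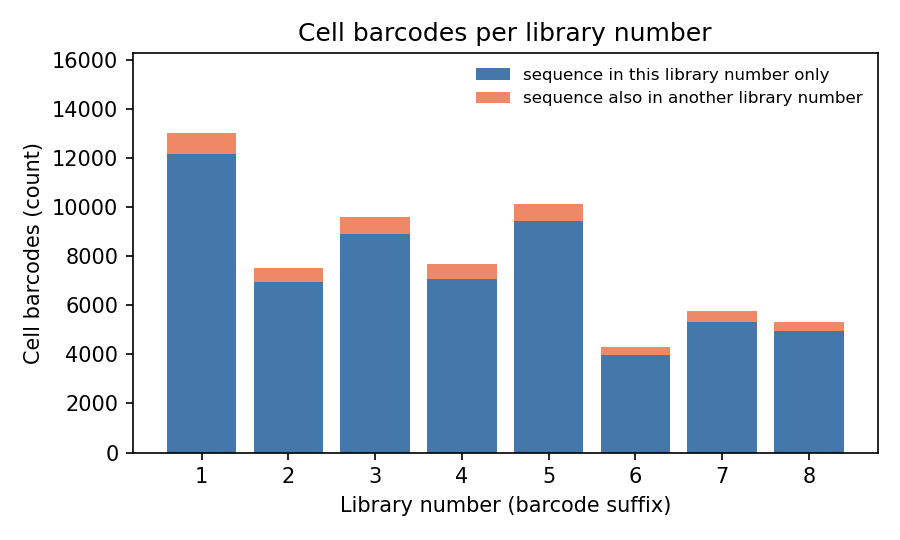
Cell barcodes (count) under each of the 8 library numbers, divided into sequences found under that number only and sequences also found under another. Library number 1 holds the most, 13018, and library number 6 the fewest, 4301.

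Barcode sequences recurred between library numbers at a rate that did not differ detectably among pairs. Of 60999 distinct sequences, 2276 (3.73%) occurred under 2 or more numbers, 39 of them under 3 numbers and 1 under 4. Over the 28 pairs there were 2359 shared sequences, which gave an estimated pool of 731136 sequences (95% interval 702215 to 761561). Observed sharing ranged from 0.80 to 1.24 times the expectation. None of the 28 pairs passed an adjusted p of 0.05 in the exact hypergeometric test, and 1 had an unadjusted p below it. That pair was library numbers 1 and 4, with 162 shared sequences (95% interval 138 to 189) against 137 expected, a ratio of 1.19 (exact p = 0.035, adjusted p = 0.98). With the pool taken from the other pairs, the lowest adjusted p was 0.69 by the same exact test. The spread over all pairs was no larger than that of shuffled library numbers (permutation p = 0.73, 1000 shuffles). The repair of the shuffles shifted their mean sharing, so this p is approximate.

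**Figure D3:**
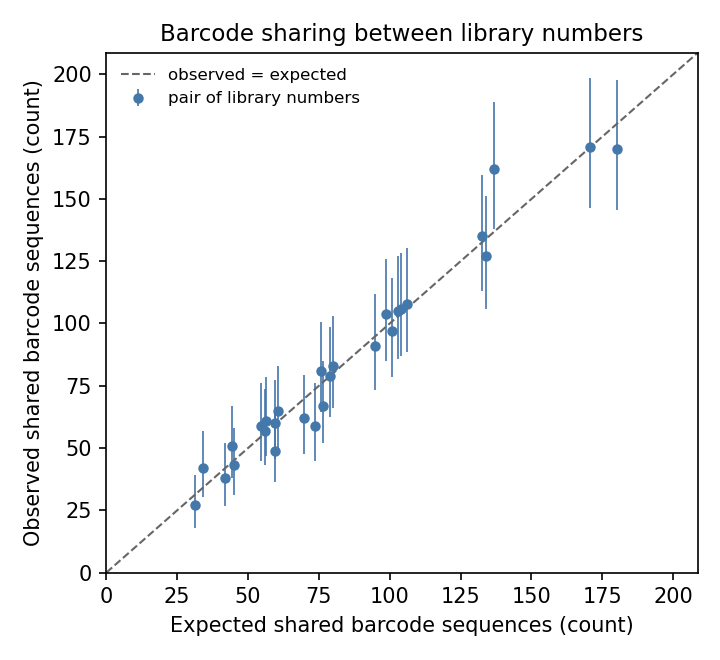
Observed against expected number of shared barcode sequences for the 28 pairs of library numbers, with 95% exact Poisson intervals as bars. The dashed line marks equality, and the observed counts lie between 0.80 and 1.24 times the expectation.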

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

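Most counts reported kept to within 1.5 times their values under the alternatives that were run. Markers with any shared 3′ word numbered 5 with 90-base words, against 14 with 50-base words and 18 with a window of 1000 bases. A longer word is by construction harder to share. Barcodes numbered 58723 when only those found in 1 library number were counted, against 63316. No pair of library numbers passed an adjusted p of 0.05 with the pool estimated without each library number in turn (pool of 719575 to 742367 sequences). The same held with shuffled library numbers, where 0 pairs had an unadjusted p below 0.05, against 1 by the exact hypergeometric test. In 1000 shuffles a lone pair could not reach an adjusted p of 0.05, so the lack of adjusted calls there tells nothing about a lone pair. The repair by random swaps does not draw the permitted shuffles evenly, so every p taken from the shuffles is approximate. Their mean sharing differed from the hypergeometric expectation. It was 141.3 against 136.7 for library numbers 1 and 4, and 31.7 against 34.0 for library numbers 6 and 7. Allowing 1 mismatch added no shared sequence to the 2359 found by identity, so that alternative tested nothing. Features numbered 27877 when only symbols carried by 1 feature were counted. Matching symbols without regard to case, or through symbols carried by 1 feature, left 81 markers listed. The alternatives for shared 3′ words and for overlap by position were chosen after the data were seen. Markers overlapped by position numbered 1 with windows of 200 and 1000 bases and with protein-coding overlaps only. Markers sharing at least 10% of 3′ words numbered 5 with 90-base words and 6 with a window of 1000 bases, where Ly6a was added. The other settings meant for the comparison of expanded cells with progenitors and for clusters were not run, since no counts were analysed. No paired analysis was possible because each group had 1 sample and no library number was tied to a group. In the pair of library numbers 1 and 4, 30 added shared barcodes were called in 18% of simulated runs, so sharing of that size would mostly be missed in that pair. Other pairs were not simulated with added sharing.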

Other observations

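A list of stem cell factor, its receptor and antigens often used to sort progenitors, chosen after the symbols had been seen, was complete with 14 of 14 genes. As 98.2% of protein-coding genes were listed, such completeness is not particular to this list. Its genes included Kit, the receptor of stem cell factor (chromosome 5, 75574916 to 75656722), Kitl, stem cell factor itself (chromosome 10, 100015630 to 100100416), and Cd34, Cd48 and Flt3. Itgam, which encodes the myeloid antigen CD11b, was the only one carried by 2 features and was singled out after its values were seen. The first lay on chromosome 7 from 128062640 to 128118491 and the second, named Gm49368 in M21, from 128062683 to 128128160. They shared 3450 exonic bases, 68.7% of the first and 71.8% of the second. None of the last 500 exonic bases of either was shared by position, while 30.1% of the 50-base words near the ends of transcripts of the first also occurred in the second. For the second feature 3.75% of words were shared, with the first and with other genes. With 90-base words the first was at 24.5% and the second at 0%. Fcgr3 and Fcgr2b, Fc gamma receptor genes, shared little or no sequence in the last 500 bases, with 0% of Fcgr3 and 1.36% of Fcgr2b 50-base words. At 90-base words both were at 0%. In a window of 1000 bases 10.3% of Fcgr3 and 4.81% of Fcgr2b 50-base words were shared with other listed genes. The list also held 5 symbols that begin with Hbb- (beta-like globin), 3 with Hba- (alpha-like globin) and 13 with mt- (mitochondrial). Of the mitochondrial ribosomal and transfer RNA genes of M21, 0 of 2 and 0 of 22 were listed.

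All tests in this part were chosen after the results were seen. The absence of Ighm concerns a gene that B lineage cells transcribe, and such cells descend from common lymphoid progenitors. That the gene is listed under another symbol was argued against, since 0 listed identifiers equalled that of Ighm in M21. A difference of annotation release alone was argued against by the counts over all M21 genes. Of the immunoglobulin and T cell receptor genes 0 of 702 were listed, against 21631 of 22028 protein-coding genes. The exact limits, 0.524% (upper) and 98.0% (lower), add nothing to these counts, since no genes were sampled. That whole gene classes were left out when the feature list was made is a candidate explanation, in line with 0 of 702 listed and with 0 of 2207 microRNA genes. As a hypothesis, lymphoid identity in these libraries may have to be read from genes such as Dntt, Il7r and Rag1, without antigen receptor transcripts. No biological explanation was tested, because a feature list does not depend on the cells.

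The sharing of barcode sequences between library numbers was weighed in the same way. Independent draws from 1 pool of barcode sequences predict 34 to 61 sequences under 3 or more library numbers (mean 47.4), and 40 were found, in line with such draws. Transfer of barcodes between particular pairs of libraries cannot be told apart from chance at this size, since the upper limit of the excess in the pair of library numbers 1 and 4 was 0.681% of the smaller library. Transfer that raised all pairs alike was not tested, because the pool size was estimated from the same pairs. No pool size from outside these data was used. The design gives no biological explanation for shared barcodes, and none was tested.

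Why there were 8 library numbers and 6 labelled samples was not tested. No library number stood apart in its number of barcodes by Dixon's test (gap of 0.333 of the range, below the 95% critical value for 8 values).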
